A study of Mus musculus with 8 samples.

How the data were processed

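Single-nucleus RNA was measured in snap-frozen cerebral cortex of female mice aged 7 months, per the labels' protocols. The labels put 4 samples in the WT group, with wild-type Ezh1 alleles and the Neurod1-Cre transgene, and 4 in the Ezh1 conditional knockout (cKO) group. Each sample gave 1 droplet library from the Chromium 3-prime v4 kit, sequenced on a NovaSeq X Plus. The deposited values were raw UMI counts per gene and nucleus barcode, which the authors made with Cell Ranger 8.0.1, per the file headers. STAR and the mm10 build were named in the submitters' processing notes. The annotation release and the settings for calling nuclei are not given in the sources used here. A UMI is a molecular tag, so each count stands for a captured molecule and not for a PCR copy. Such 3-prime counts come mainly from transcript ends and internal A-rich stretches of unspliced RNA, so they do not show which exon of a gene is present.

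The libraries held 36412340 to 55938416 UMIs and 10025 to 12028 barcodes. All 8 libraries differed from each other by more than counting noise, with chi-square values of 5.76 to 40.5 per degree of freedom between pairs, so none was a copy of another. Separate preparations of 1 sample could differ by more than counting noise too, so this does not show independent samples. Each library was counted as a replicate. Nuclei with at least 500 genes, at least 1000 UMIs and at most 5% mitochondrial UMIs were kept, 74095 of 86316 barcodes. Scrublet scores were computed per library. Its automatic threshold marked 0% to 7.48% of nuclei and under 0.1% in 4 libraries, where it did not work. In Ezh1 cKO 1 it also moved with the settings of the numerical library, but the nuclei with the highest scores there were the same. Therefore the 8% of nuclei with the highest score were removed from every library, 5929 in all. The remaining 68166 nuclei were clustered together without batch integration, in scanpy 1.11.5 with leidenalg 0.10.2, from 3000 variable genes, 30 principal components, 20 nearest neighbours and a resolution of 1.

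Clusters were named from marker lists set before the data were examined. The scoring rule on those markers was set afterwards. It asked for at least 3 detected markers, for no lead of another class, and for a subclass name also for a marker among the cluster's 10 leading genes. Clusters with 3 or more mitochondrial or ribosomal protein genes among those 10 stayed unnamed. A class other than the excitatory one needed a share of 0.6 of its markers and a mean log2 fold of 1.5 over the other nuclei. The excitatory class needed a share of 0.5, no fold of its own, and every other class below 0.8. It therefore holds clusters whose excitatory markers were lower on average than in the other nuclei, such as cluster 17 (4 of 8 detected, mean log2 fold -0.4). Names are written with "like" because they come from this match and not from the authors. Excitatory clusters without a layer name kept their number. Coordinates came from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, in which 32158 of 32285 gene identifiers were found.

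Raw counts were summed per library over each class and each excitatory subclass with at least 30 nuclei in every library. Endothelial-like nuclei fell below that number and were not tested. The sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test with robust dispersion), with group as the sole term. P-values were adjusted by the Benjamini-Hochberg method over the genes of each fit, and an adjusted p below 0.05 was called. Standard errors of log2 fold changes were taken as the fold change over the square root of F. A second model over the 16 sums of excitatory and inhibitory nuclei, with library as a block, tested whether the effect of genotype differed between these classes.

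A total of 25 gene lists were set before the data were examined, on Polycomb and trithorax genes, developmental regulators, neuronal and glial markers, stress and quality. They were tested with camera in limma 3.58.1 on voom-weighted log2 CPM with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Summed list levels, shares of nuclei and library measures were compared with a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286. DESeq2 1.42.0 was run as another tool, and adjusted p-values it left empty were not counted.

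Named genes followed a rule set before the data were examined. It took Ezh1, Ezh2, Eed, Suz12, Kdm6a, Kdm6b and Cdkn2a, and the called genes of the excitatory class with the largest changes. It also took the gene of each list with the smallest p, the 3 largest called rises and falls of each other class and subclass, and 4 members of each list past the threshold. Genes whose changes are named in Results outside this rule are said to be chosen after their values were seen.

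The test was tested on simulated counts made from the means and library sizes of each class, with 200 genes changed. In the excitatory simulation of 17057 genes, 53.1% of genes changed 1.5-fold and 87.5% of genes changed 2-fold were recovered, with 12 false calls. The matching shares for inhibitory nuclei were 55.1% and 85.7% of the changed genes among 12475. Only 22.2% of genes changed 2-fold were recovered in fibroblast-like nuclei. The self-test of the difference between classes recovered 69.6% of genes changed 2-fold in 1 class (135 of 194), with 13 false calls.

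Alternatives chosen before the data were examined were DESeq2, RLE factors, library size alone, no filter and a stricter filter on low counts (50 counts in 4 libraries), the replicate number as a block, each library left out, a stricter filter on nuclei (1000 genes, 1% mitochondrial UMIs) and doublets kept. For the excitatory class, nuclei chosen by their own counts, equal numbers of nuclei per cluster and 1 surrogate variable from sva 3.50.0 were added. Chosen after seeing the data were a block and separate fits for replicates 1 and 2 against replicates 3 and 4, a fit of the named layer subclasses alone, and the lists with equal numbers of nuclei per cluster. Surrogate splits of the 8 libraries into other groups of 4 numbered 35, the real one included.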

Results

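Nuclei were profiled from the cerebral cortex of female mice aged 7 months, in 4 WT libraries with the Neurod1-Cre transgene and 4 Ezh1 cKO libraries. Ezh1 encodes a histone methyltransferase subunit of Polycomb repressive complex 2 (PRC2), which deposits H3K27me3, and Neurod1-Cre acts in the lineage of cortical excitatory neurons. The design asks what the loss of Ezh1 does to gene expression in neurons that no longer divide. The libraries held 36412340 to 55938416 UMIs, and 7655 to 9620 nuclei per library were kept. The median UMI count per nucleus was 4254 ± 626 in WT and 3980.5 ± 447 in Ezh1 cKO libraries (SD, n = 4 each, exact permutation p = 0.514). The median mitochondrial share of UMIs was 0.139% ± 0.0132 and 0.106% ± 0.0466 (SD, n = 4 each, exact permutation p = 0.2). The labels do not say that samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

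The 68166 nuclei formed 40 clusters. Excitatory-neuron-like nuclei numbered 43156 and inhibitory-neuron-like nuclei 6900. There were 4611 astrocyte-like, 4075 oligodendrocyte-like, 1714 striatal-projection-neuron-like, 1231 oligodendrocyte-precursor-like, 815 microglia-like and 597 fibroblast-like nuclei. Clusters with too few or mixed markers, or led by mitochondrial and ribosomal protein genes, stayed unnamed and held 3766 nuclei. Their share was 6.82% ± 1.53 in WT and 4.38% ± 2.40 in Ezh1 cKO libraries (SD, n = 4 each, exact permutation p = 0.143). Cluster 12, led by mitochondrial and ribosomal protein genes, held 2069 of them (median 1470 UMIs). Of its nuclei, WT replicates 1 to 4 held 18.5%, 17.45%, 16.7% and 13.3%. The Ezh1 cKO replicates held 1.93%, 6.43%, 8.99% and 16.8% in that order. Within the excitatory class, layer subclasses were led by Cux2 and Ccbe1 (L2/3 IT), Rorb and Rspo1 (L4/5 IT), Etv1 and Deptor (L5 IT), Npr3 and Erg (L5 ET), Tshz2 and Slc17a8 (L5/6 NP), Oprk1 and Gnb4 (L6 IT), Foxp2 and Syt6 (L6 CT), and Ccn2 and Svil (L6b). Excitatory sums of replicates 1 and 2 scored below those of replicates 3 and 4 in both groups on the first principal component, which held 37% of the variance. In the order of their replicate numbers, the Ezh1 cKO libraries scored -36.6, -21.0, 17.3 and 27.4 there, and the WT libraries -15.6, -1.69, 6.64 and 23.7. Cluster 17 made up 8.89% and 7.86% of excitatory nuclei in Ezh1 cKO replicates 1 and 2, but 0.0835% and 0.0565% in replicates 3 and 4. The contrast was weaker in the WT group, with 5.85%, 3.13%, 2.77% and 0.642% in replicates 1 to 4. The labels give no batch for this difference.

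Ezh1 itself, on chromosome 11 (GRCm38, 101191115 to 101226463, minus strand), was counted at 42.3 ± 2.11 CPM in WT and 33.8 ± 2.54 CPM in Ezh1 cKO excitatory-neuron-like nuclei (SD, n = 4 each). All 4 Ezh1 cKO libraries, at 32.2 to 37.6 CPM, lay below all 4 WT libraries, at 40.2 to 45.1 CPM. The log2 fold change was -0.32 with a standard error of 0.0675 and an edgeR adjusted p of 0.195, which missed the threshold. Unadjusted, the edgeR p was 6.54e-04, and the exact permutation p was 0.0286, the smallest possible. Ezh1 was named before the data were examined, but its adjusted p covers all genes tested. Ezh1 passed with DESeq2 (adjusted p = 0.0185), with 1 surrogate variable (adjusted p = 0.0187) and with replicates 1 and 2 against 3 and 4 as a block (adjusted p = 0.0475). Replicates 1 and 2 alone and replicates 3 and 4 alone both gave -0.32 (edgeR adjusted p = 0.381 and 0.319). Inhibitory-neuron-like nuclei had 41.7 ± 1.51 and 31.9 ± 2.22 CPM, a log2 fold change of -0.38 with a standard error of 0.0984 (edgeR adjusted p = 0.200, unadjusted p = 8.37e-04, exact permutation p = 0.0286). The change did not differ detectably between these classes, with a difference of -0.08 on the log2 scale and a standard error of 0.0889 (edgeR adjusted p = 0.886). Oligodendrocyte-like nuclei had a log2 fold change of -0.31 (edgeR adjusted p = 0.975), astrocyte-like nuclei -0.16 (0.996), striatal-projection-neuron-like nuclei -0.02 (0.9998) and fibroblast-like nuclei 0.21 (0.999). Ezh1 lay below the count filter and was not tested by edgeR in oligodendrocyte-precursor-like nuclei, with 34.0 ± 8.23 and 23.4 ± 4.44 CPM (SD, n = 4 each, exact permutation p = 0.0857). The same held in microglia-like nuclei, with 59.0 ± 9.45 and 92.3 ± 44.4 CPM (SD, n = 4 each, exact permutation p = 0.171). The labels do not say which part of Ezh1 is deleted, so a 3-prime count may check nothing about the allele. Cntnap1, the gene next to Ezh1, had a log2 fold change of -0.25 with a standard error of 0.0618 in excitatory-neuron-like nuclei (edgeR adjusted p = 0.296).

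**Figure D1:**
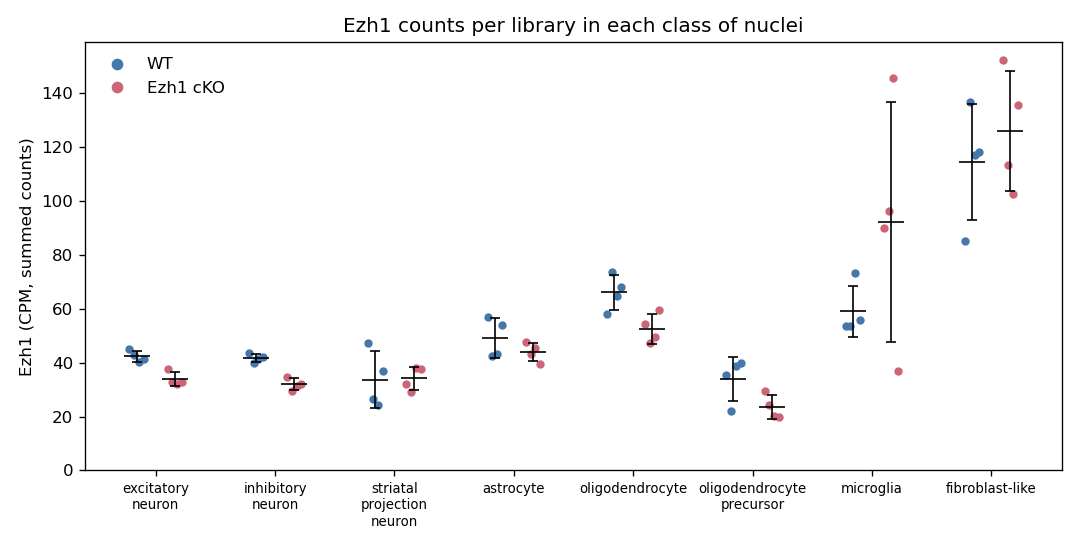
Ezh1 level (CPM of counts summed per library, linear axis from 0) in 8 classes of nuclei, with 1 point per library, WT in blue and Ezh1 cKO in red; horizontal bars are means and whiskers 1 SD (n = 4). In excitatory-neuron-like nuclei the Ezh1 cKO points lie at 32.2 to 37.6 CPM, below the WT points at 40.2 to 45.1 CPM.

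In excitatory-neuron-like nuclei, 5 genes rose and 1 fell in the Ezh1 cKO among 17237 tested (edgeR). Cacng4, an auxiliary subunit of AMPA receptors, rose from 6.0 ± 0.328 to 12.1 ± 0.900 CPM (SD, n = 4 each), a log2 fold change of 1.01 with a standard error of 0.0895 (edgeR adjusted p = 0.00507). It lies within 10 Mb of Ezh1 on chromosome 11, and flanking DNA of the targeted allele was not excluded for it (Other observations). Cacng4 is also among the 10 leading genes of cluster 21, the oligodendrocyte-precursor-like nuclei. Cacng4 was called in L2/3 IT-like nuclei too. There the other leading genes of the precursor class were higher by 39.3% of the log2 change that its RNA would bring if it caused the rise. For the pooled excitatory class this was not tested. Gm2762, a gene model of unknown function, rose from 9.60 ± 1.40 to 20.5 ± 1.40 CPM, by 1.10 on the log2 scale (edgeR adjusted p = 0.00773). Vgll2, a cofactor of TEAD transcription factors known from muscle, and its neighbour Ros1, a receptor tyrosine kinase, rose by 2.34 (edgeR adjusted p = 0.0181) and 1.85 (0.0300) from low levels of 0.210 and 0.901 CPM. They lie on chromosome 10 at 52022502 to 52028471 and at 52045721 to 52195244. Stag3, a cohesin subunit of meiosis, rose by 1.28 (edgeR adjusted p = 0.0349). Platr25, a non-coding RNA, fell by 0.43 from 26.7 to 19.9 CPM (edgeR adjusted p = 0.0487). In each of these genes all 4 Ezh1 cKO libraries lay on the same side of all 4 WT libraries.

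The other PRC2 core genes were measured and not called. Ezh2, the other catalytic subunit, had a log2 fold change of -0.05 (standard error 0.0634), Eed -0.01 (0.0679) and Suz12 -0.04 (0.0680). The H3K27 demethylase genes Kdm6a and Kdm6b had -0.15 (0.0592) and -0.35 (0.235). Their edgeR adjusted p-values ran from 0.543 to 0.983. Cdkn2a, a cell cycle inhibitor and known PRC2 target, stayed below the filter with 71 counts, 27 in WT and 44 in Ezh1 cKO libraries, or 0.218 ± 0.0560 and 0.361 ± 0.0600 CPM (SD, n = 4 each).

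Cacng4 and Gm2762 stayed past the threshold in all 8 fits that left out 1 library. Stag3 and Platr25 were lost in all 8, with adjusted p-values of up to 0.150 and 0.180. Vgll2 was lost without any of the 4 WT libraries, Ezh1 cKO 1 or Ezh1 cKO 3 (up to 0.107). Ros1 was lost without WT 1, 2 or 3, or Ezh1 cKO 1, 3 or 4 (up to 0.132). The count was 2 without WT 2, WT 3, Ezh1 cKO 1 or Ezh1 cKO 3, 3 without WT 1 or WT 4, and 4 without Ezh1 cKO 2. DESeq2 called 100 genes, 77 of them higher. With replicates 1 and 2 against 3 and 4 as a block edgeR called 73 genes, and with the replicate number as a block 87. Replicates 1 and 2 alone gave 53 genes and replicates 3 and 4 alone gave 0 by edgeR, with 1341 genes at an unadjusted p under 0.05; DESeq2 was not run on these subsets.

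**Figure D2:**
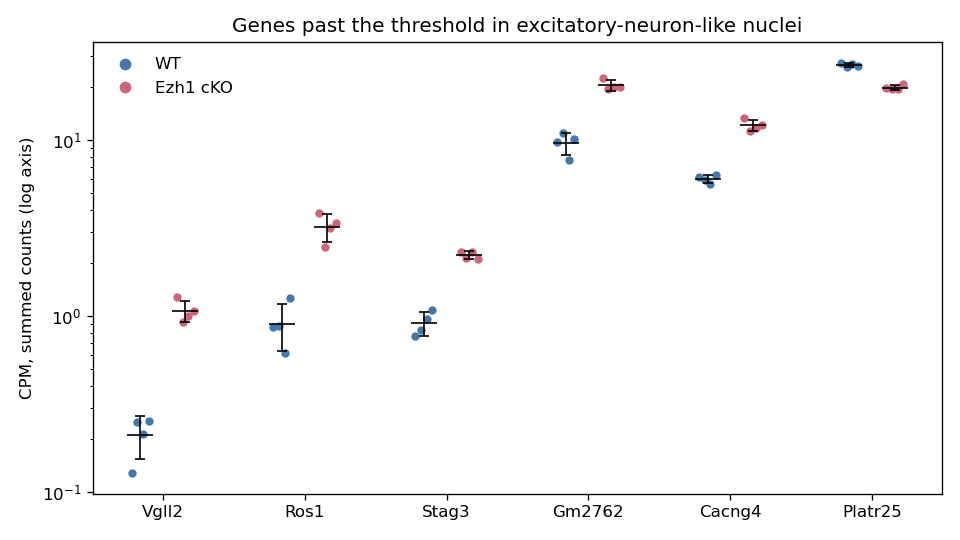
Level of the 6 genes past the threshold in excitatory-neuron-like nuclei (CPM of summed counts, log axis), with 1 point per library, WT in blue and Ezh1 cKO in red; horizontal bars are means and whiskers 1 SD (n = 4). Cacng4 stands at 6.0 CPM in WT and 12.1 CPM in Ezh1 cKO libraries, and Platr25 at 26.7 and 19.9 CPM.

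Of the 25 gene lists, 24 had members past the count filter in excitatory-neuron-like nuclei, and 10 passed camera with the preset correlation. Lower in the Ezh1 cKO were cytosolic ribosomal protein genes (52 of 55 members lower, camera adjusted p = 2.89e-05), mitochondrially encoded genes (13 of 13, 4.4e-05) and upper-layer cortical neuron genes (13 of 15, 0.00120). Also lower were glutamatergic synapse genes (38 of 50, 0.00794), voltage-gated ion channel genes (28 of 40, 0.0298), PRC2 subunits other than Ezh1 (9 of 10, 0.0298) and activity-regulated genes (22 of 29, 0.0377). Higher were microglia genes (13 of 13, 1.51e-04), oligodendrocyte genes (12 of 13, 9.10e-04) and deep-layer cortical neuron genes (18 of 20, 0.0135). All 10 were lost with an estimated correlation (adjusted p = 0.623 for each), and the smallest fry adjusted p for a shift in 1 direction was 0.480. Over all genes tested, 0 list members and 6 of 17237 genes of the class passed by edgeR, with 1413 genes of the class at an unadjusted p under 0.05. The median log2 fold change was -0.18 for ribosomal, -0.36 for mitochondrial, 0.41 for microglia and 0.42 for oligodendrocyte genes, and -0.08 for the PRC2 subunits. With 1 library left out it ran from -0.30 to 0.00 for ribosomal genes (highest without Ezh1 cKO 1), -0.56 to -0.22 for mitochondrial, 0.22 to 0.57 for microglia and 0.29 to 0.66 for oligodendrocyte genes. For the PRC2 subunits it ran from -0.11 without Ezh1 cKO 4 to -0.04 without Ezh1 cKO 1. With the same number of nuclei from each cluster, an alternative for the lists added after the data were seen, 4 lists passed, the mitochondrial, ribosomal, oligodendrocyte and microglia lists (camera adjusted p = 1.18e-06, 1.84e-05, 0.00157 and 0.00851). These 4 were lost there too with an estimated correlation (camera adjusted p = 0.787 for each). The upper-layer list had a median log2 fold change of -0.15 before and 0.02 after (adjusted p = 0.481), and the deep-layer list 0.16 and 0.06 (0.377). That fit changes the balance of clusters and the number of nuclei together, so it cannot tell which of them moved both lists. The share of L4/5 IT-like nuclei was 21.8% in WT and 17.2% in Ezh1 cKO libraries (exact permutation p = 0.0857). The deep-layer list was also higher within L4/5 IT-like and L2/3 IT-like nuclei (Other observations). Shares between subclasses do not enter those fits directly. Nuclei or free RNA of deep layers mixed into these subclasses could still carry such shares in, and stay open. The synapse (camera adjusted p = 0.0981), channel (0.188), PRC2 (0.302) and activity-regulated lists (0.481) missed too in the fit with equal numbers. Their medians also shrank, from -0.06 to -0.02 for synapse, -0.05 to -0.04 for channel, -0.08 to -0.05 for PRC2 and -0.13 to -0.02 for activity-regulated genes. That fit holds fewer nuclei, 2658 per library.

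Members of these lists are given with values, since none passed over all genes tested. Rorb and Mef2c, transcription factors of upper layers, had log2 fold changes of -0.52 and -0.40, Whrn -0.29 and Calb1 -0.24. Among deep-layer genes Sox5 had 0.17, Cplx3 0.41 and Crym 0.33. Among synapse genes Dlg3 had -0.21, Dlg1 -0.23, Rims1 -0.17 and Homer3 0.63, and among channel genes Kcnh5 had -0.26, Cacnb4 -0.21, Cacna2d3 -0.23 and Cacna1h 0.38. The immediate early genes Arc and Egr3 had -0.36 and -0.22, Homer1 -0.32 and Inhba 0.23. Of PRC2 accessory genes, Rbbp4 had -0.14, Phf1 -0.18, Mtf2 -0.10 and Rbbp7 -0.12. Of the microglial transcripts, Tmem119 was at 0.233 CPM in WT and 0.533 CPM in Ezh1 cKO libraries, Selplg had a log2 fold change of 1.05, P2ry12 0.19 and Cx3cr1 0.22, and of the oligodendrocyte transcripts Cldn11 had 0.74, St18 0.58, Mag 0.51 and Trf 0.44. For the quality lists, mt-Nd6 had -0.48, mt-Nd4l -0.42, mt-Co2 -0.36 and mt-Nd4 -0.32, and Rps2 -0.30, Rps23 -0.27, Rpl4 -0.22 and Rps6 -0.21. Over all nuclei kept, Ezh1 cKO 4 went the other way, with the highest median mitochondrial share of the 8 libraries (0.172%). Without WT 3 the ribosomal, mitochondrial and microglia lists passed, 3 in all, and the oligodendrocyte and upper-layer lists had an adjusted p of 0.0789. Without Ezh1 cKO 1 the ribosomal list was lost (adjusted p = 0.770), with the channel (0.0554), PRC2 (0.367) and activity-regulated lists (0.102). The PRC2 list was also lost without WT 1 (adjusted p = 0.0795) and without WT 3 (0.0789). The deep-layer list was lost without Ezh1 cKO 3 (0.107), the synapse list without Ezh1 cKO 4 (0.135) and WT 1 (0.0795), and the activity-regulated list also without WT 1, Ezh1 cKO 3 and Ezh1 cKO 4 (up to 0.780).

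The remaining 14 lists missed the threshold of camera. Adjusted p-values were 0.0523 for striatal and hippocampal neuron genes, 0.116 for interneuron genes, 0.124 for H3K27 demethylases, acetyltransferases and trithorax genes, 0.224 for reactive microglia genes and 0.233 for heat shock and stress genes. They were 0.262 for imprinted genes, 0.262 for vascular genes, 0.301 for developmental transcription factors, 0.301 for cell cycle inhibitors and apoptosis genes, 0.327 for astrocyte genes and 0.370 for reactive astrocyte genes. Interferon-stimulated genes had 0.807, PRC1 subunits 0.931 and genes beside Ezh1 0.983, although fry's test for changes in either direction gave an adjusted p of 0.0480 for the last. Some of these passed in other settings. The striatal and hippocampal list did with no filter on low counts (adjusted p = 0.0367) and without WT 2 (0.0464), WT 4 (0.0245), Ezh1 cKO 1 (0.00859) or Ezh1 cKO 4 (0.0255), each time as higher. The interneuron list did, also as higher, without WT 2 (0.0253), WT 4 (0.00263) or Ezh1 cKO 1 (0.00859). The H3K27 list did as lower with no filter (0.0499) and without WT 2 (0.0344) or Ezh1 cKO 1 (0.0218). The developmental list passed without WT 2 (0.0464) or Ezh1 cKO 3 (0.0466) and the astrocyte list without WT 2 (0.0227), as higher, and the heat shock list without Ezh1 cKO 4 (0.0175), as lower. Adjusted over the list alone, 2 cell cycle and apoptosis genes rose, led by Pmaip1 (log2 fold change 1.45, standard error 0.343), which promotes apoptosis. Adjusted over the list alone, 1 reactive microglia gene, Trem2 (0.382 to 0.904 CPM), and 1 imprinted gene, Gnasas1 (2.36, standard error 0.474), rose. Gnasas1 overlaps Gnas in antisense, and whether counting used the strand is not given in the sources used here. Adjusted over the list alone, 0 members of every other tested list passed.

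Hox genes, silenced by Polycomb in the forebrain, were close to undetected. Their 39 members together had 8 counts in WT and 16 in Ezh1 cKO excitatory-neuron-like nuclei, or 0.0674 ± 0.0143 and 0.138 ± 0.0564 CPM (SD, n = 4 each, exact permutation p = 0.0571). Without Ezh1 cKO 1 the difference was 0.0895 CPM with an exact permutation p of 0.0286, the smallest that the remaining libraries can give. Only Ezh1 cKO 1 (0.0805 CPM) and WT 2 (0.0840 CPM) overlapped, so leaving out either of them separates the groups. Of the 24 counts in all, 11 came from Hoxa7. Developmental transcription factors, 110 genes of other tissues and of embryonic patterning, summed to 7.21 ± 1.34 and 8.43 ± 1.01 CPM (SD, n = 4 each, exact permutation p = 0.171). Neither exact permutation p over all 8 libraries was below 0.05.

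By edgeR, L4/5 IT-like, L2/3 IT-like and L5 IT-like nuclei and cluster 7 each gave more calls than the 6 of the pooled class, and the other 6 subclasses did not. By DESeq2 only L4/5 IT-like nuclei did (143 against 100). Over 10 excitatory subclasses edgeR made 135 calls, 118 rises and 17 falls, in 108 genes, of which 22 were called in at least 2 subclasses and 4 also in the class. L4/5 IT-like nuclei had 61 rises and 8 falls, L2/3 IT-like nuclei 30 and 2, L5 IT-like nuclei 10 and 2, cluster 7 10 and 2, L5 ET-like nuclei 4 and 1, L6 CT-like nuclei 3 and 0, and cluster 16 0 and 2. At an unadjusted p under 0.05 more genes were higher than lower in L4/5 IT-like (847 and 515) and L2/3 IT-like nuclei (606 and 440), but not in L5/6 NP-like nuclei (204 and 204) or cluster 16 (205 and 219). Epha10, an ephrin receptor, fell in 4 subclasses (L2/3 IT, L4/5 IT, L5 IT and cluster 7), with log2 fold changes of -0.85 to -0.64. L3mbtl4, whose MBT domains bind methylated histones, rose in 4 (L4/5 IT, L5 IT, L5 ET and cluster 7) by 0.65 to 1.23, and Gfra1, a GDNF coreceptor, rose in 3 (L2/3 IT, L4/5 IT and L5 IT) by 0.94 to 1.88. The other leading genes of cluster 23, where Gfra1 is highest among the other excitatory clusters, were higher in these 3 by 185.1%, 139.2% and 135.3% of the log2 change that nuclei of cluster 23 would bring if they caused the rise of Gfra1. Epha10, L3mbtl4 and Gfra1 were singled out after their values were seen.

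In L2/3 IT-like nuclei Spef2, a protein of sperm flagella, rose by 1.84 (edgeR adjusted p = 0.00428), as did the mitotic cyclin Ccnb1 (1.81) and the Wnt inhibitor Dkk2 (1.35 to 3.88 CPM), while Epha10 (-0.65, adjusted p = 8.11e-04) and Lamp5 (-0.51) fell. In L4/5 IT-like nuclei Cyp4f16, a cytochrome P450 of a family with close paralogs, rose by 2.79 (edgeR adjusted p = 0.00523), Spef2 by 2.08 and the axon guidance effector Dpysl5 by 1.80. Gm45341 (-1.83), Ppm1m (-1.38) and Egfl6 (-1.32) fell there. In L5 IT-like nuclei Gfra1 (1.88), Plppr1 (4.60 to 18.0 CPM) and L3mbtl4 (1.09, edgeR adjusted p = 0.00418) rose, and Epha10 (-0.64) and Efr3a (-0.49) fell. Sfmbt2, a Polycomb-group protein with MBT domains, rose in L5 ET-like nuclei from 17.5 to 46.1 CPM (log2 fold change 1.49, edgeR adjusted p = 0.00186), beside Rasgrp2 (1.17) and Ptprt (0.89), while Ltbp1 (-0.76) fell. Sfmbt2 was also called as a rise in L4/5 IT-like nuclei (0.89). Prss12 (0.97), Inpp4b (0.78) and Cntnap5a (0.60) rose in L6 CT-like nuclei. In cluster 7, led by Dnah14 and Galnt14, Ros1 (2.13), Fbn2 (1.65) and Gm34567 (1.54) rose, and Epha10 (-0.85) and B230209E15Rik (-0.56) fell. In cluster 16, led by Tshz2 and Vwc2l, mt-Cytb (-1.35, edgeR adjusted p = 6.41e-05) and 9630014M24Rik (59.8 to 21.4 CPM) fell.

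L5/6 NP-like, L6 IT-like and L6b-like nuclei had 0 calls by edgeR, with 408, 395 and 359 genes at an unadjusted p under 0.05 and 1, 1 and 0 calls by DESeq2. With replicates 1 and 2 against 3 and 4 as a block they had 19, 1 and 0, with replicates 1 and 2 alone 82, 4 and 1, and with replicates 3 and 4 alone 0, 0 and 6. L5/6 NP-like nuclei had 9 calls without WT 2 and 9 without Ezh1 cKO 4, and L6 IT-like nuclei 5 without WT 4 and 6 without Ezh1 cKO 4. Of the 30 calls named by the rule in subclasses, 12 stayed past the threshold whichever library was left out. These were Spef2 in both subclasses, Cyp4f16, Dpysl5, Ppm1m, Plppr1, L3mbtl4, Sfmbt2, Inpp4b, Ros1, mt-Cytb, and Epha10 in L2/3 IT-like nuclei. With 1 library left out the count ran from 24 to 74 in L4/5 IT-like and 13 to 38 in L2/3 IT-like nuclei, both lowest without Ezh1 cKO 3. It ran from 5 to 23 in L5 IT-like nuclei, 2 to 21 in cluster 7, 2 to 7 in L5 ET-like nuclei, 1 to 11 in L6 CT-like nuclei and 1 to 12 in cluster 16. Replicates 1 and 2 alone gave 8, 0, 1, 11, 2, 1 and 9 calls in these 7, and replicates 3 and 4 alone 23, 22, 0, 7, 4, 21 and 5. The total of 135 became 80 without WT 1, 81 without WT 3 and 49 without Ezh1 cKO 3. Replicates 1 and 2 alone gave 119 calls with 60.5% rises, and replicates 3 and 4 alone gave 88 with 80.7% rises, against 87.4% over all libraries.

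**Figure D3:**
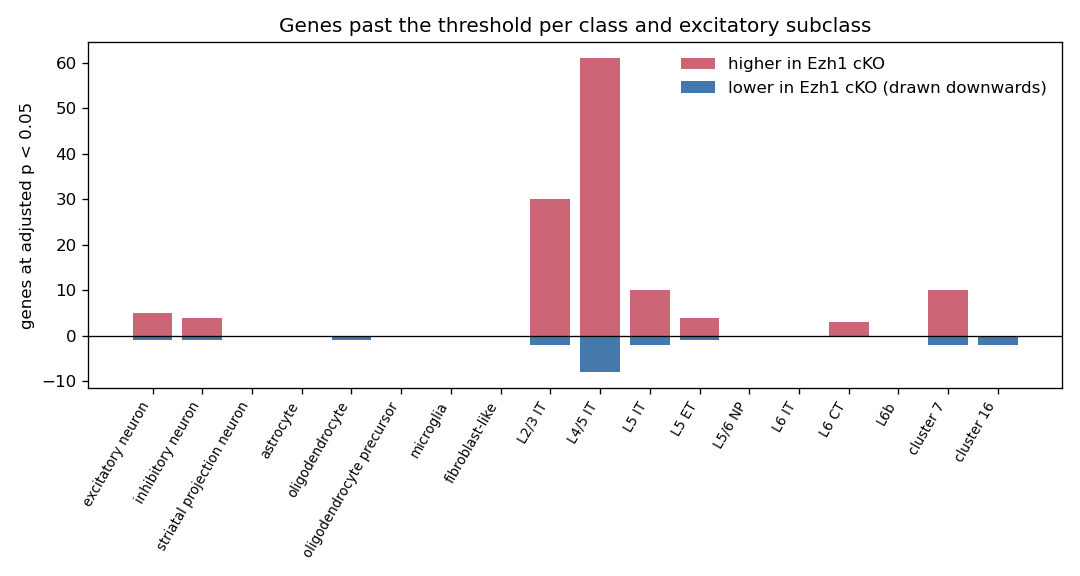
Number of genes at an adjusted p under 0.05 (edgeR, 4 Ezh1 cKO against 4 WT libraries) in each class and excitatory subclass, with rises drawn upwards in red and falls downwards in blue. L4/5 IT-like nuclei have the tallest bars, with 61 rises and 8 falls.

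Inhibitory-neuron-like nuclei, outside the lineage in which Neurod1-Cre is known to act, had 4 rises and 1 fall among 12650 genes tested (edgeR). Sfmbt2 rose from 49.9 ± 5.24 to 103 ± 9.18 CPM (SD, n = 4 each), a log2 fold change of 1.04 with a standard error of 0.0886 (edgeR adjusted p = 7.84e-07). In excitatory-neuron-like nuclei it had 0.97 with a standard error of 0.212 (edgeR adjusted p = 0.281). The change in Sfmbt2 did not differ detectably between these classes (difference 0.06, edgeR adjusted p = 0.977). Spag6, an axoneme protein with the near-identical copy Spag6l, which makes its count uncertain, rose by 2.77 (edgeR adjusted p = 0.0203). Plod2, a lysyl hydroxylase of collagen, rose by 0.86 (0.0180), and St6galnac3, a sialyltransferase named after its value was seen, by 0.47 (0.0419). Tmem108, a neuronal membrane protein, fell by 0.40 (0.0419). Sfmbt2 stayed past the threshold in all 8 fits with 1 library left out; Spag6 was lost in 3, Plod2 in 3 and Tmem108 in 6 of them. The count was 1 without WT 4 or Ezh1 cKO 2, 3 without WT 2 or WT 3, 8 without WT 1 or Ezh1 cKO 3, and 10 without Ezh1 cKO 4. DESeq2 called 14 genes, 1 higher and 13 lower, and replicates 1 and 2 alone gave 20 and replicates 3 and 4 alone 7.

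Glial and other classes gave few calls. Slc4a10, a sodium-coupled bicarbonate transporter of neurons, fell in oligodendrocyte-like nuclei from 156.5 to 96.9 CPM, a log2 fold change of -0.71 with a standard error of 0.127 (edgeR adjusted p = 0.0367). DESeq2 made 0 calls there, as did edgeR with the stricter filter on nuclei. The main edgeR fit had 392 genes at an unadjusted p under 0.05. These nuclei had a median of 1358 UMIs, and free RNA from neurons was not tested as a source of this neuronal transcript. The call on Slc4a10 was lost without WT 1, WT 3, WT 4, Ezh1 cKO 2 or Ezh1 cKO 3 (adjusted p up to 0.433), and the count of genes was 3 without Ezh1 cKO 1 and 6 without Ezh1 cKO 4. By edgeR, 0 genes passed in striatal-projection-neuron-like, astrocyte-like, oligodendrocyte-precursor-like, microglia-like and fibroblast-like nuclei. The counts at an unadjusted p under 0.05 were 309, 417, 195, 98 and 84, and DESeq2 called 1, 0, 0, 0 and 0. Without Ezh1 cKO 4 or WT 1, oligodendrocyte-precursor-like nuclei had 6 and 2 calls, and without Ezh1 cKO 3 striatal-projection-neuron-like nuclei had 1. Replicates 1 and 2 alone gave 34 calls in striatal-projection-neuron-like, 6 in astrocyte-like, 9 in oligodendrocyte-like and 8 in oligodendrocyte-precursor-like nuclei. Replicates 3 and 4 alone gave 9 in astrocyte-like, 6 in oligodendrocyte-like and 21 in microglia-like nuclei.

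The effect of genotype differed between excitatory-neuron-like and inhibitory-neuron-like nuclei for 19 of 12592 genes (edgeR), with 1051 at an unadjusted p under 0.05. For Epha10 the log2 fold change was -0.58 in excitatory and -0.11 in inhibitory nuclei, a difference of 0.46 with a standard error of 0.0784 (edgeR adjusted p = 0.0156). For Tmem108 it was 0.03 and -0.40, a difference of -0.45 (0.00616), and for Spag6 -0.03 and 2.77, a difference of 2.81 (0.0240). Rasgrp2, called as a rise in L5 ET-like nuclei, had a difference of -0.91. Mcc and Ttc28, chosen after their values were seen, had -0.43 and -0.54. The number of such genes was 6 without WT 3, 9 without WT 1 or Ezh1 cKO 2, 11 without Ezh1 cKO 3, 12 without Ezh1 cKO 1 and 54 without Ezh1 cKO 4. Plod2 (difference 0.65, edgeR adjusted p = 0.151) and St6galnac3 (0.35, 0.188), called in the inhibitory class, missed the threshold of this test. So did Cacng4 (-0.77, 0.1505), called in the excitatory class.

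No share of nuclei passed the threshold after adjustment. The smallest exact p possible is 0.0286, and the class that reached it had an adjusted p of 0.400, so 1 class could not pass alone. Endothelial-like nuclei made up 0.792% ± 0.156 of WT and 0.444% ± 0.196 of Ezh1 cKO nuclei (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.400), with every Ezh1 cKO library below every WT library. Pericyte-like or smooth-muscle-like nuclei made up 0.414% ± 0.0853 and 0.246% ± 0.0749 (exact permutation p = 0.0571, adjusted p = 0.400). Excitatory nuclei made up 62.9% ± 2.57 and 63.6% ± 0.904 (exact permutation p = 0.743), and inhibitory nuclei 10.1% ± 0.435 and 10.1% ± 0.302 (exact permutation p = 1). Dentate-granule-neuron-like nuclei made up 0.230% ± 0.169 and 1.05% ± 0.792 (exact permutation p = 0.143, adjusted p = 0.5). Among excitatory nuclei, L4/5 IT-like nuclei made up 21.8% ± 2.08 and 17.2% ± 3.50 (exact permutation p = 0.0857, adjusted p = 0.971), and cluster 20 1.28% ± 1.36 and 4.67% ± 3.37 (exact permutation p = 0.143, adjusted p = 0.971).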

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

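The splits of the libraries, the comparison of even splits, the test with equal numbers of nuclei per cluster, the rises in subclasses of 1 cluster and the test of how much higher the other leading genes of a source stood were chosen after the results were seen.

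More genes rose than fell in the excitatory subclasses, 118 of 135 calls. Uneven numbers of nuclei per cluster were argued against as the whole cause in the pooled class, where 91.3% of the calls rose with equal numbers. The same held for the 5 subclasses with calls that hold 1 cluster, where 27 of 34 calls rose. L4/5 IT-like and L2/3 IT-like nuclei, with 69 and 32 of the 135 calls, hold more than 1 cluster each. No fit with equal numbers per cluster was run within these subclasses, so uneven numbers stay open there. A loss of repression with Ezh1 may add to the rises in the subclasses and was not tested on them. In a related test of weakly expressed genes in the pooled class, the share of rises was not beyond that of other splits (Other observations). Nuclei of other excitatory clusters and free RNA from other classes stay open. Of the rises, 63.6% were among the 200 genes leading another cluster, against 6.41% of the genes tested. In another class 62.7% had at least 5 times the CPM, against 14.0%. Against either as the whole cause, the other leading genes of the source were higher by a median of 47.9% (clusters) and 19.2% (classes) of the log2 change that the called rises would need, although choosing called genes raises that need. For 14 of 75 rises, those of Gfra1, Inpp4b and Cntnap5a among them, it was more than 100% for clusters, so mixed-in nuclei stay open as their whole cause, while this held for 0 of 71 for classes.

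Ezh1 counts were lower by a similar factor in excitatory-neuron-like and inhibitory-neuron-like nuclei. Free RNA from excitatory nuclei was argued against as the main source of the difference in inhibitory nuclei, since it could bring 5.19% of it. That value takes the lowest level that an excitatory marker had in inhibitory nuclei as the limit for free RNA, and other markers were higher, up to Tbr1 at 26.0% of its level in excitatory nuclei. Deletion outside the Neurod1 lineage, or a difference between the mouse lines, may account for it, and neither was tested.

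Microglia and oligodendrocyte lists were higher and mitochondrial and ribosomal lists lower in excitatory-neuron-like nuclei of the Ezh1 cKO, but the astrocyte list missed (camera adjusted p = 0.327) and all 4 were lost with an estimated correlation (adjusted p = 0.623 for each). Free RNA in proportion to the glial nuclei of a library was argued against, since the level of the oligodendrocyte list in excitatory nuclei had a Pearson r of -0.264 with the share of oligodendrocyte-like nuclei over the 8 libraries (exact permutation p = 0.531, Spearman rho = -0.262, exact permutation p = 0.536), and that of the microglia list -0.295 (p = 0.488, rho = -0.238, p = 0.582). Adjusted over these 2 relations, p was 0.531 for each, and r was -0.21 and -0.703 without the 2 libraries farthest from the median. The part of Ezh1 cKO 1 cannot be told apart from that of genotype, since 3 of the 4 lists remained past the threshold without it and the ribosomal list did not. Droplets with markers of 2 classes were present: the unnamed clusters 27 and 31, led by microglial and oligodendrocyte genes, held 604 and 477 nuclei. Free RNA in other amounts, mixed droplets left in the class, handling of the tissue and a change in the neurons may all contribute. None of these was tested.

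Chance could not be excluded for the counts of genes per class, over the subclasses together and for the difference between classes, or for that of the lists. Among the 10 subclasses taken singly, only the real split gave as many as 69 in L4/5 IT-like nuclei (highest other 38), 2 gave as many as 32 in L2/3 IT-like nuclei (61), and 4 did in each of the other 5 subclasses with calls. In L4/5 IT-like and L2/3 IT-like nuclei these highest others were the split of replicates 1 and 2 against 3 and 4, and the remaining splits gave at most 1. Of 35 splits of the 8 libraries into groups of 4, the real one included, 2 gave as many genes as the real 6 in excitatory-neuron-like nuclei (highest other 213, the remaining 33 gave 0), 3 as many as 5 in inhibitory-neuron-like nuclei (75) and 8 as many as 1 in oligodendrocyte-like nuclei (26). For the subclasses 3 splits gave as many as 135 (491), for the difference between classes 3 as many as 19 (59), and for the lists 11 as many as 10 (14). In the classes with 0 calls all 35 did, with highest counts of 24 in striatal-projection-neuron-like, 55 in astrocyte-like, 55 in oligodendrocyte-precursor-like, 33 in microglia-like and 236 in fibroblast-like nuclei. The split of replicates 1 and 2 against 3 and 4 gave 213, 491 and 59, which points to a structure of the samples that the labels do not name. Among the 18 splits that spread replicates 1 and 2 evenly over both groups, as the real one does, only the real one gave as many as 6, 5, 135 and 19 in the excitatory and inhibitory classes, the subclasses and the difference between classes (highest others 0, 4, 9 and 0). For oligodendrocyte-like nuclei 3 did (3), and for the lists 7 (14). These 18 are too few for a share under 5%, since the smallest is 5.56%. With replicates 1 and 2 against 3 and 4 as a block, 73 genes were called in the excitatory class and 325 in the subclasses.

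In 16 of 312 groups of 4 libraries, 1 library lay far from the other 3, about the 1 in 20 that chance gives. The gap to the nearest library, as a share of the group's range, was 0.877 for the share of ependymal-like or choroid-plexus-like nuclei in Ezh1 cKO 4 (0.352% against 0.129%), 0.851 for that of L6 CT-like nuclei in WT 4 (13.2% against 10.5%) and 0.858 for that of cluster 7 in WT 4 (9.03% against 6.83%). For the CPM of Ezh1 it was 0.888 in excitatory nuclei of Ezh1 cKO 1 (37.6 against 32.8), 0.885 in microglia-like nuclei of WT 3 (73.1 against 55.8) and 0.837 in L2/3 IT-like nuclei of WT 2 (46.2 against 42.5). In excitatory nuclei it was 0.838 for Suz12 in WT 1 (49.4 against 43.9 CPM), 0.854 for Kdm6a (90.8 against 84.6), 0.835 for Platr25 (20.8 against 19.6) and 0.970 for Bcl11b (74.7 against 103.7) in Ezh1 cKO 4, 0.851 for Cacna2d3 in Ezh1 cKO 1 (946.2 against 1049) and 0.968 for Cplx3 in Ezh1 cKO 3 (1.17 against 0.958). In subclasses it was 0.894 for Epha10 in L2/3 IT-like nuclei of WT 2 (122.2 against 136.5 CPM) and 0.893 in those of Ezh1 cKO 4 (79.4 against 87.1), 0.904 for L3mbtl4 in L5 IT-like nuclei of WT 3 (25.3 against 18.5) and 0.836 for Inpp4b in L6 CT-like nuclei of Ezh1 cKO 2 (119.4 against 149.9).

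The log2 effect of genotype differed between inhibitory and excitatory nuclei in 19 genes by a test of the difference itself (edgeR). The effect in inhibitory nuclei was higher for Spag6 by 2.81, Skap2 by 1.09, Cpne9 by 0.94, Hs3st2 by 0.535, Jph1 by 0.46 and Epha10 by 0.46. The differences of the others were -1.001 for Adgra3, -0.91 for Rasgrp2, -0.73 for Bcan, -0.72 for Grip1os2, -0.71 for A530058N18Rik, -0.64 for Mpp7, -0.59 for Grip1, -0.54 for Ttc28, -0.46 for Cntnap4, -0.45 for Tmem108, -0.43 for Mcc, -0.35 for Esrrg and -0.33 for Fam110b. Cntnap4 had a log2 fold change of 0.34 in excitatory and -0.10 in inhibitory nuclei, and Grip1 0.505 and -0.07.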

How the results depend on the processing

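The block and the separate fits for replicates 1 and 2 against 3 and 4, the fit of named layers alone, and equal numbers of nuclei per cluster for the lists, were chosen after the data were seen. The cause was not tested for any change below except that separate fits hold 4 libraries.

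With DESeq2 the counts were 100 in excitatory, 14 in inhibitory, 1 in striatal-projection-neuron-like and 0 in oligodendrocyte-like nuclei, and 259 in the subclasses. With no filter on low counts they were 34, 69, 7 and 7, with 3 in astrocyte-like and 3 in oligodendrocyte-precursor-like nuclei, 819 in the subclasses and 189 for the difference between classes. Rises were then 72.8% of the subclass calls, against 87.4% in the main result. A stricter filter on low counts gave 2 in inhibitory nuclei and 64 in the subclasses, doublets kept 2 in inhibitory nuclei, and a stricter filter on nuclei 0 in oligodendrocyte-like nuclei. In excitatory nuclei library size alone gave 12, equal numbers of nuclei per cluster 23, 1 surrogate variable 116 and named layers alone 38. With replicates 1 and 2 against 3 and 4 as a block the counts were 73 in excitatory, 26 in inhibitory and 4 in oligodendrocyte-like nuclei and 325 in the subclasses. Replicates 1 and 2 alone gave 53, 20 and 9, with 34 in striatal-projection-neuron-like, 6 in astrocyte-like and 8 in oligodendrocyte-precursor-like nuclei. Replicates 3 and 4 alone gave 0 in excitatory nuclei (edgeR, 1341 at an unadjusted p under 0.05), 9 in astrocyte-like, 6 in oligodendrocyte-like and 21 in microglia-like nuclei, and 88 in the subclasses. With an estimated correlation 0 lists passed camera, and with equal numbers of nuclei per cluster 4 did. Ezh1 passed with DESeq2 (-0.32, adjusted p = 0.0185), the block of replicates 1 and 2 against 3 and 4 (-0.32, 0.0475) and 1 surrogate variable (-0.33, 0.0187).

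The replicate numbers did not pair the samples by the rule that every same-numbered pair correlates above 0.1: the correlations were 0.439, 0.125, 0.0925 and 0.408. All 4 WT libraries correlated best with the Ezh1 cKO library of their own number, but Ezh1 cKO 2 correlated best with WT 1 and Ezh1 cKO 3 with WT 4. With the replicate number as a block the counts were 87 in excitatory, 20 in inhibitory and 5 in oligodendrocyte-like nuclei and 438 in the subclasses (42 in L5/6 NP-like and 6 in L6 IT-like nuclei), and Ezh1 passed (-0.32, adjusted p = 0.0363), as did the striatal and hippocampal list with camera (0.00539). The difference between classes was not run with that block, since the library block contains it.

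With 1 library left out, the counts ran from 2 to 6 in excitatory, 1 to 10 in inhibitory, 0 to 1 in striatal-projection-neuron-like, 0 to 6 in oligodendrocyte-like and 0 to 6 in oligodendrocyte-precursor-like nuclei, 49 to 167 in the subclasses, 6 to 54 for the difference between classes and 3 to 15 for the lists. The Hox difference ran from 0.0450 to 0.0895 CPM. Of 1240 values with 1 library left out, 982 kept their direction and side of the threshold, or stayed within the spread or 1.5 times the count, and of 1506 under other alternatives 1312 did. By the direction of the test for lists and the sign for others, 0 of these that passed before or after turned. Other values that passed in neither did turn, such as the heat shock list (a median log2 fold change of 0.10 without Ezh1 cKO 1). The self-test recovered 22.2% of genes changed 2-fold in fibroblast-like, 67.4% in oligodendrocyte-precursor-like, 76.1% in striatal-projection-neuron-like, 77.1% in oligodendrocyte-like, 78.05% in microglia-like, 80.85% in astrocyte-like, 85.7% in inhibitory and 87.5% in excitatory nuclei.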

Other observations

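The test of genes near Ezh1 was chosen only after the result was seen.

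Mitochondrially encoded transcripts, which in nuclei come from RNA outside them, were lower in the Ezh1 cKO as a list in other classes too. The median log2 fold change was -0.31 in inhibitory-neuron-like nuclei (camera adjusted p = 3.67e-06), -0.47 in astrocyte-like, -0.62 in oligodendrocyte-like, -0.67 in oligodendrocyte-precursor-like and -0.67 in microglia-like nuclei. With an estimated correlation these were lost, with an adjusted p of 0.503, 0.683, 0.489, 0.2405 and 0.309. In cluster 16 the median was -1.29 (camera adjusted p = 3.72e-33), which held with an estimated correlation (adjusted p = 0.0433). Deep-layer genes were higher as a list in L4/5 IT-like nuclei (median 0.37, camera adjusted p = 3.22e-05) and L2/3 IT-like nuclei (0.31, 0.00315), and both were lost with an estimated correlation (adjusted p = 0.728 and 0.733).

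A hypothesis was that the genes called in excitatory subclasses move the same way in inhibitory nuclei. Of 97 such genes tested there, 68 did (70.1%), but 4 of the 35 splits gave as large a share, the highest other 75.3%. Library-wide differences may give as much: of the 100 genes with the smallest p in excitatory nuclei 86 kept their direction, and 6 of the 35 splits gave as many, the highest other 94.

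Another hypothesis was that changes come in chromosomal neighbours. Among 380 genes with an unadjusted p under 0.01 in excitatory nuclei, 16 pairs were neighbours, against a mean of 3.70 and a highest of 14 in 10000 shuffles of gene order (permutation p = 1e-04, the smallest these can give). They included, chosen after their values were seen, Vgll2, Ros1 and Dcbld1 on chromosome 10, Col6a2 and Col6a1, and Cntnap1 and Ezh1. Shared regulation may be a source, but paralogs such as Vmn2r84 to Vmn2r87 can share reads, and 3 of the 35 splits gave as many pairs, the highest other more than 100.

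Flanking DNA of the targeted allele was tested as a source of changes near Ezh1. Within 10 Mb, 26 of 281 genes (9.25%) had an unadjusted p under 0.05, against 8.175% elsewhere (Fisher's exact p = 0.510), so no excess over all genes was detected. However, 1 of these 281 was called, Cacng4 (107732357 to 107794557), the gene with the smallest p of the 6 called, and fry's test for changes in either direction gave an adjusted p of 0.0480 for the list of genes beside Ezh1. Flanking DNA was therefore not excluded for Cacng4.

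It was also asked whether weakly expressed genes lose repression. Below 5 CPM 117 of 134 genes with an unadjusted p under 0.01 rose in excitatory nuclei (87.3%), against 133 of 246 above it (54.1%). In 6 of the 35 splits as large a share lay on 1 side, the highest other 94.1%, so the share was not beyond that of other splits. The same held among the 18 splits that spread replicates 1 and 2 evenly over both groups, a comparison chosen after the result was seen, where 4 gave as large a share.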
